A study of Mus musculus with 6 samples.

How the data were processed

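RNA from CD19+ T1 B cells, sorted from spleens of 1-week-old WT, Xid and Btk KO mice, was amplified in 2 rounds, labelled with biotin and hybridised (100 ng of cRNA) to MOE430 2.0 arrays, 2 for each of 3 genotypes. Per the submitters' processing notes, the deposited values are MAS5 signal intensities, 1 per probe set and array; no version, settings or detection calls are given. The values were checked to be on a linear scale, with each array scaled so that the mean between the 2nd and the 98th percentile was 100. Without detection calls, signal over background could not be read per probe set, so precision was judged from the spread between the 2 arrays of a genotype, which left 3 residual degrees of freedom.

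The 64 control probe sets were left out of the tests, leaving 45037 probe sets. Of these, 34945 carry 1 gene symbol (18193 genes; 34741 matched by Entrez identifier to the reference table, used for names only), 932 carry several and 9160 none. Probe sets with several symbols or none were tested but not named. Values were taken as log2(signal + 16), and the 50% of probe sets with the highest mean over all arrays (22518) were tested. Linear models were fitted to all 6 arrays in R 4.3.3 with limma 3.58.1 (statmod 1.5.0), with moderated variances that follow a trend with intensity. The comparisons were Btk KO vs WT, Xid vs WT, Btk KO vs Xid and the mean of Btk KO and Xid (Btk-defective) vs WT. P-values were adjusted by the Benjamini-Hochberg method in each comparison, and an adjusted p under 0.05 was called. Probe sets were also counted that differed by at least 1 on the log2 scale with no overlap between the arrays of the 2 groups.

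The 28 gene lists were tested with the camera method of limma on 11478 genes, each by its probe set with the highest mean, with a preset correlation of 0.01 and adjustment over 112 tests. They were repeated with a correlation estimated for each list. The lists covered BCR signalling components, BCR inhibitory receptors and phosphatases, Tec kinases other than Btk, immediate early and BCR-induced genes, NF-kB targets, apoptosis regulators, the early, follicular, marginal zone with B-1 and plasma cell stages, MHC class II presentation, interferon response, S phase, mitosis, chemokine receptors and adhesion, heat shock, chromosomal neighbours of Btk, immunoglobulin genes, ribosomal proteins, the respiratory chain, and markers of T cells, NK cells, neutrophils, macrophages, dendritic cells, erythroid cells, megakaryocytes and stroma. Members were also adjusted over their list alone.

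The comparisons, the alternatives and the rule for named genes were set before the data were examined. The rule named Btk; for Btk KO vs WT, Xid vs WT and Btk KO vs Xid, the 12 genes with the largest rise and the 12 with the largest fall among calls with a log2 change of at least 1; and up to 4 members of each list with the smallest p. Where fewer than 12 passed, places went to the smallest unadjusted p among genes that changed by at least 1 without overlap, given as values that did not pass. Genes outside this rule are said to be chosen after their values were seen. The correlation between the Btk KO and Xid changes was compared with 100 simulations of unchanged groups that share controls.

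The tests were tried on simulated data in 5 runs with 100 changed probe sets of each size. At a log2 change of 1, 5% were recovered in Btk KO vs WT, 5.4% in Xid vs WT and 4.8% in Btk KO vs Xid, and at 2 these were 75.8, 75.4 and 78.6%, with a mean of 3, 3.8 and 4.8 false calls. The simulation gave each probe set the same spread in every genotype. In the data the SD of the log2 difference between replicates was 0.631 in Btk KO, 0.311 in WT and 0.310 in Xid. These rates are therefore not those of groups with such spreads. A shift of 0.5 in a list of 20 genes was found in 5 of 5 runs, and a mean of 2.8 of 100 unchanged lists had an unadjusted p under 0.05. Both counts used the unadjusted p of camera, so they do not give the error rate after adjustment over the list tests. The simulated genes were also drawn independently of each other. Correlations estimated for the real lists were, for example, 0.682 for follicular genes, 0.99 for neutrophil markers and -0.027 for the marginal zone list. The counts therefore do not give the error rate for lists of correlated genes. Alternatives were other pseudocounts, quantile normalization, median centring, other filters on low values, no variance trend, array weights, 1 probe set per gene, a fit on the 2 groups compared, a replicate block, other list tests, and leaving out each array in turn.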

Results

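Gene expression was measured in CD19+ transitional type 1 (T1) B cells, the stage at which B cells reach the spleen from the bone marrow. The cells were sorted by flow cytometry from spleens of 1-week-old mice at a purity above 92%. There were 6 MOE430 2.0 arrays in 3 genotypes of 2 arrays each. WT mice were of the CBA strain, Xid mice carry a substitution in the membrane-binding domain of Btk, and Btk knockout (Btk KO) mice lack the gene after 9 generations of backcrossing to CBA. Btk is the Tec family kinase that relays signals from the B cell receptor (BCR). The labels do not say whether the 2 samples of a genotype came from separate animals, so the p-values measure only the spread between these samples. The number of arrays limited the precision of every value.

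Btk itself separated the knockout from the other genotypes on every array. Its signal was 159 and 189 on the 2 Btk KO arrays, 1230 and 1041 on the WT arrays, and 1064 and 1079 on the Xid arrays. Group means ± SD (n = 2) were 174 ± 21.4 in Btk KO, 1136 ± 134 in WT and 1072 ± 11.1 in Xid. The log2 change was -2.60 ± 0.165 (SE) in Btk KO vs WT (limma, adjusted p = 0.0144) and -0.08 ± 0.165 in Xid vs WT (adjusted p = 0.957). The position of the probe set relative to the deleted part of the gene is not known. A probe outside that part would test nothing, but the signal was low on both knockout arrays, as their labels require. The Btk KO vs WT call was lost without either WT array or either Xid array, with log2 changes between -2.72 and -2.48. It was also lost with a replicate block (-2.60, limma adjusted p = 0.061).

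**Figure D1:**
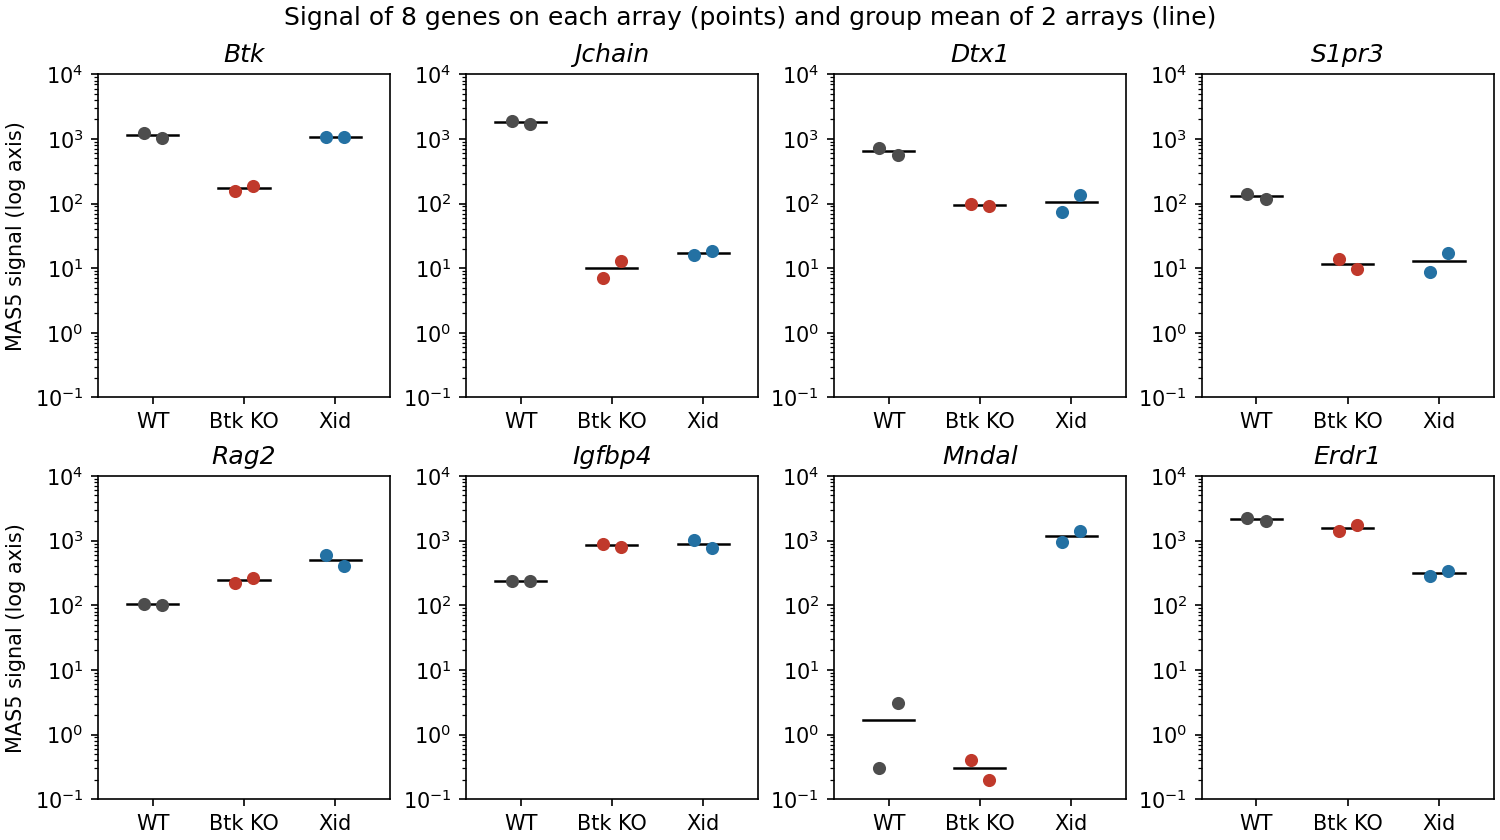
MAS5 signal on a log axis of Btk, Jchain, Dtx1, S1pr3, Rag2, Igfbp4, Mndal and Erdr1 on each array (points) with the mean of the 2 arrays of a genotype (line). Btk was low only in Btk KO, at 159 and 189; Jchain was low in both Btk KO and Xid, and Mndal was high only in Xid, at a mean of 1178.

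The 2 Btk KO arrays differed from each other more than the arrays of the other genotypes did. The SD of the log2 difference between replicates was 0.631 in Btk KO, 0.311 in WT and 0.310 in Xid. Btk KO replicate 1 had higher medians than replicate 2 in 8 of 8 lists of other cell types. On the log2 scale the differences were 1.72 for T cell markers, 1.97 for NK cell markers, 3.18 for granulocyte markers, 1.90 for macrophage markers and 2.18 for erythroid markers. It had lower medians in 6 of 6 B cell lists, by -1.01 for immunoglobulin genes and -0.84 for follicular genes. The granulocyte gene Ngp had a signal of 4460 and 1307 on the Btk KO arrays, 3592 and 4817 on the WT arrays, and 4817 and 3941 on the Xid arrays.

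**Figure D2:**
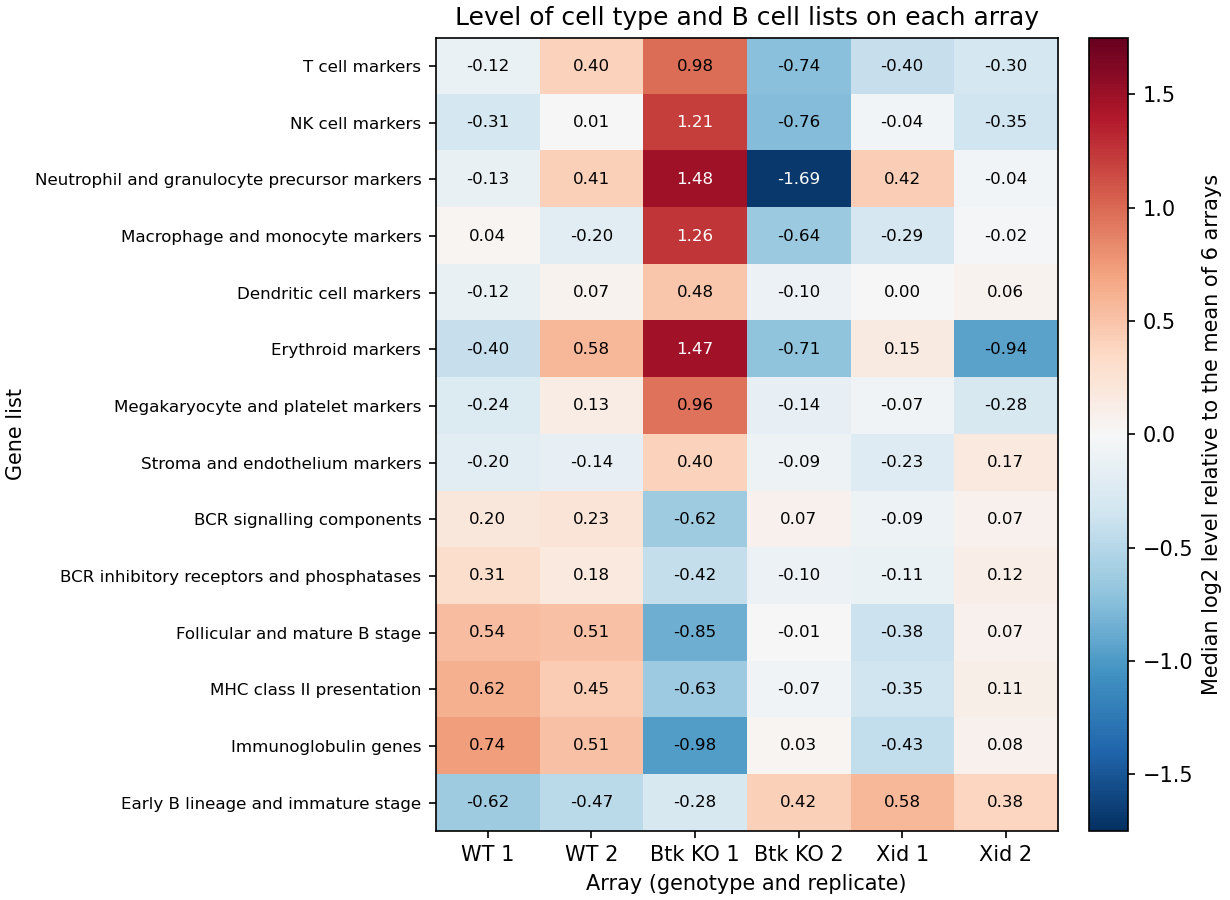
Median log2 level of 8 lists of other cell types and 6 B cell lists on each array, relative to the mean of 6 arrays (colour and printed value). Btk KO replicate 1 had the highest level in each of the 8 lists of other cell types and the lowest in 5 of the 6 B cell lists.

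Btk KO vs WT asked what the loss of the kinase changes in T1 cells. As lists, genes of later B cell stages were lower and genes of earlier stages higher with a preset correlation, which was not called with an estimated correlation (follicular adjusted p = 0.508, early 0.674). Single genes passed rarely. Jchain, which encodes the chain that joins IgM and IgA into multimers, fell from a signal of 1822 ± 139 (SD, n = 2) in WT to 10 ± 4.24 in Btk KO, a log2 change of -6.15 ± 0.203 (SE, adjusted p = 0.000365). Its size depends on the pseudocount, because the mean Btk KO signal lay below 16, and was -4.67 with a pseudocount of 64. LOC664787 (-3.20 ± 0.260, adjusted p = 0.0377) and Btk also fell, but LOC664787 did not pass with a pseudocount of 1 (adjusted p = 0.152). The other 21 of the 24 genes named for this comparison did not pass. Of these, 9 had lower values, among them 3 genes of the marginal zone and B-1 list. These were the sphingosine-1-phosphate receptor S1pr3 (-2.38, adjusted p = 0.0632), the transcription factor Zbtb32 (-1.92, 0.0632, with 0.63 at its other probe set) and the Notch regulator Dtx1 (-2.56, 0.0717). The remaining 12 had higher values, with the smallest p for Igfbp4 (1.76, adjusted p = 0.0717), and the other probe sets of Ddx54, Apba1, Tmsb10 and Ganab had values of opposite sign, as had 1 of the 2 others of Neo1. With a pseudocount of 64, St8sia6, S1pr3 and Zbtb32 passed as well. Limma called 4 of 22518 probe sets (0 higher, 4 lower), and 3412 had an unadjusted p under 0.05, where chance gives 1126. Single arrays set that count. It was 311 without Btk KO replicate 1 and 2685 without Btk KO replicate 2, each with the 4 calls among them, and 1 without either WT or either Xid array, namely Jchain. At a log2 change of at least 1 with no overlap between arrays, 590 probe sets differed, 316 higher and 274 lower (205 and 341 after quantile normalization, 168 and 438 after median centring). Chance alone leaves 33.33% of unchanged probe sets without overlap, whatever the size of the difference. The chance rate for both criteria together was not estimated.

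Gene lists of B cell stages moved apart in Btk KO. Genes of the follicular and mature stage were lower for 19 of 19 members, with a median log2 change of -0.90 (camera, adjusted p = 2.63e-12; adjusted p = 0.508 with an estimated correlation). Adjusted over the list alone, 14 of them fell, among them Ly86 (-1.56 ± 0.249), Zfp318 (-1.36 ± 0.324) and the receptor gene Cd180 (-0.72 ± 0.184). MHC class II presentation was lower for 14 of 14 genes (median -0.98, adjusted p = 4.37e-11; adjusted p = 0.508 with an estimated correlation), and 11 fell over the list alone, including H2-Eb1 (-0.82 ± 0.118) and the class II transactivator Ciita (-1.24 ± 0.295). Of 16 immunoglobulin genes, 10 fell and 1 rose over the list alone (median -1.15, adjusted p = 8.21e-09; adjusted p = 0.508 with an estimated correlation); Iglv1 had a change of -3.62 ± 0.555 and Ighm of -0.72 ± 0.143. The marginal zone and B-1 list had a median of -0.58, with 5 of 19 genes lower over the list alone, including S1pr3, Dtx1 and Plac8 (adjusted p = 6.28e-08; adjusted p = 0.25 with an estimated correlation). In the plasma cell and secretory list, 4 of 19 fell over the list alone, Jchain, Hsp90b1, Derl3 and Pdia4 (median -0.51, adjusted p = 7.69e-09; adjusted p = 0.25 with an estimated correlation). The early B lineage list went the other way, with a median of 0.52 (adjusted p = 0.000309; adjusted p = 0.674 with an estimated correlation). Of its 23 genes, 5 rose over the list alone, among them Erg (1.40 ± 0.239), the recombinase gene Rag2 (1.12 ± 0.227) and Socs2 (1.37 ± 0.222), and 1 fell. The gene against the trend of its list was Igha (0.90 ± 0.271) among immunoglobulin genes and Cd24a (-0.42 ± 0.112) among early genes, both named after their values were seen. In the fit of 1 probe set for each of 11478 genes, limma called Jchain alone among the members of these lists over all genes. At an unadjusted p under 0.05, 14 follicular, 12 class II and 11 immunoglobulin genes were lower. Without Btk KO replicate 1, with higher markers of other cell types than replicate 2, the medians were -0.56 (follicular), -0.49 (class II), -0.66 (immunoglobulin) and 0.89 (early), all still called. The follicular median was -1.41 without Btk KO replicate 2, when the early list no longer passed (0.17, adjusted p = 0.366).

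Genes that act in or answer to BCR signalling were also lower in Btk KO. Immediate early and BCR-induced genes had a median of -0.50 with 31 of 34 below 0 (adjusted p = 1.99e-09; adjusted p = 0.508 with an estimated correlation). Over the list alone 8 fell, among them the BCR-induced transcription factors Nr4a1 (-1.44 ± 0.214) and Egr3 (-2.46 ± 0.389), Fosb (-1.38 ± 0.255) and Myc (-0.89 ± 0.165). NF-kB targets had a median of -0.62, and 1 of 26, the cyclin gene Ccnd2 (-1.55 ± 0.276), fell over the list alone (adjusted p = 2.94e-06; adjusted p = 0.508 with an estimated correlation). BCR signalling components had a median of -0.43 (adjusted p = 1.75e-06; adjusted p = 0.508 with an estimated correlation); limma called 0 of 29 over the list alone, and 10 were lower at an unadjusted p under 0.05, such as Cd79b (-0.61) and Blk (-1.45). Inhibitory receptors and phosphatases had a median of -0.59 (adjusted p = 7.5e-05; adjusted p = 0.447 with an estimated correlation), with Ptpn22 (-1.05 ± 0.202) and Ptpn6 (-0.86 ± 0.192) lower over the list alone. Chemokine receptors and adhesion genes had a median of -0.20 (adjusted p = 0.0104; adjusted p = 0.447 with an estimated correlation), and limma called 0 of 19, with 3 lower at an unadjusted p under 0.05. Over all genes, limma called 0 members of these 5 lists. Without Btk KO replicate 1, the array with higher markers of other cell types than replicate 2, the medians were -0.20 (immediate early), -0.13 (NF-kB), -0.24 (BCR components) and -0.32 (inhibitory), each still called. Immediate early genes had -0.89 and BCR components -0.71 without Btk KO replicate 2. The chemokine list was not called without Btk KO replicate 2 (-0.19, adjusted p = 0.0719) or WT replicate 2 (-0.15, 0.0901), and its median was -0.30 without WT replicate 1.

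Cell cycle and interferon genes had higher medians in Btk KO. Mitosis and G2/M genes had a median of 0.45, with 28 of 29 above 0 (adjusted p = 7.28e-07; adjusted p = 0.655 with an estimated correlation), and interferon response genes one of 0.45 (adjusted p = 0.00489; adjusted p = 0.694 with an estimated correlation). Limma called 0 members of either list over the list alone, and 11 mitosis and 5 interferon genes were higher at an unadjusted p under 0.05. DNA replication and S phase genes had a median of 0.25 (adjusted p = 0.0321; adjusted p = 0.859 with an estimated correlation), which was -0.04 without Btk KO replicate 1. Without WT replicate 1 the S phase list did not pass (0.17, adjusted p = 0.392), and its median was 0.50 without Btk KO replicate 2 and 0.40 without WT replicate 2. The interferon list did not pass without Btk KO replicate 2 (0.34, adjusted p = 0.62). Cytosolic ribosomal protein genes had a median of -0.47 (adjusted p = 4.08e-24; adjusted p = 0.25 with an estimated correlation), and of -0.04, still called, after quantile normalization. Over the list alone 33 of 48 fell, such as Rpl13a (-0.61 ± 0.106) and Rpl38 (-0.50 ± 0.095), and limma called 0 over all genes, with 35 lower at an unadjusted p under 0.05. Respiratory chain genes had a median of -0.04 (adjusted p = 0.0354; adjusted p = 0.727 with an estimated correlation), but quantile normalization called them in the opposite direction (0.11, adjusted p = 0.0114). That median was -0.13 without Btk KO replicate 1, 0.03 without Btk KO replicate 2 (adjusted p = 0.862), -0.03 without WT replicate 1 (0.0928) and -0.08 without WT replicate 2. Median centring shifts all changes by -0.145 in Btk KO vs WT, -0.174 in Btk KO vs Xid and 0.029 in Xid vs WT, whereas the list tests compare a list with the other genes.

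The remaining lists did not pass in Btk KO vs WT. Medians were 0.25 for the chromosomal neighbours of Btk (adjusted p = 0.0999; Armcx6 higher and Xkrx lower over the list alone), -0.14 for apoptosis regulators (0.146), -0.02 for heat shock genes (0.408) and 0.02 for the other Tec kinases (0.572), whose mean was -0.10. In the apoptosis list, the survival gene Bcl2 (-1.27 ± 0.235) and the death effector gene Bid (-1.28 ± 0.261) fell over the list alone. Markers of other cell types had medians of -0.07 for T cells (adjusted p = 0.769; Cd2 fell over the list alone), 0.46 for NK cells (0.298), -0.31 for neutrophils and their precursors (0.255), 0.49 for macrophages (0.354), 0.14 for dendritic cells (0.796), 0.22 for erythroid cells (0.873), 0.56 for megakaryocytes (0.271) and 0.23 for stroma (0.298). Without Btk KO replicate 1 these were -0.87 for T cells, -0.70 for NK cells, -1.84 for neutrophils, -0.53 for macrophages and -0.86 for erythroid cells. They were -0.148 for dendritic cells, 0.0388 for megakaryocytes and 0.105 for stroma, and the median of the neighbour list was 0.22. These medians rest on 1 Btk KO array, and genes of a list can move together (estimated correlation 0.99 for neutrophil markers).

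**Figure D3:**
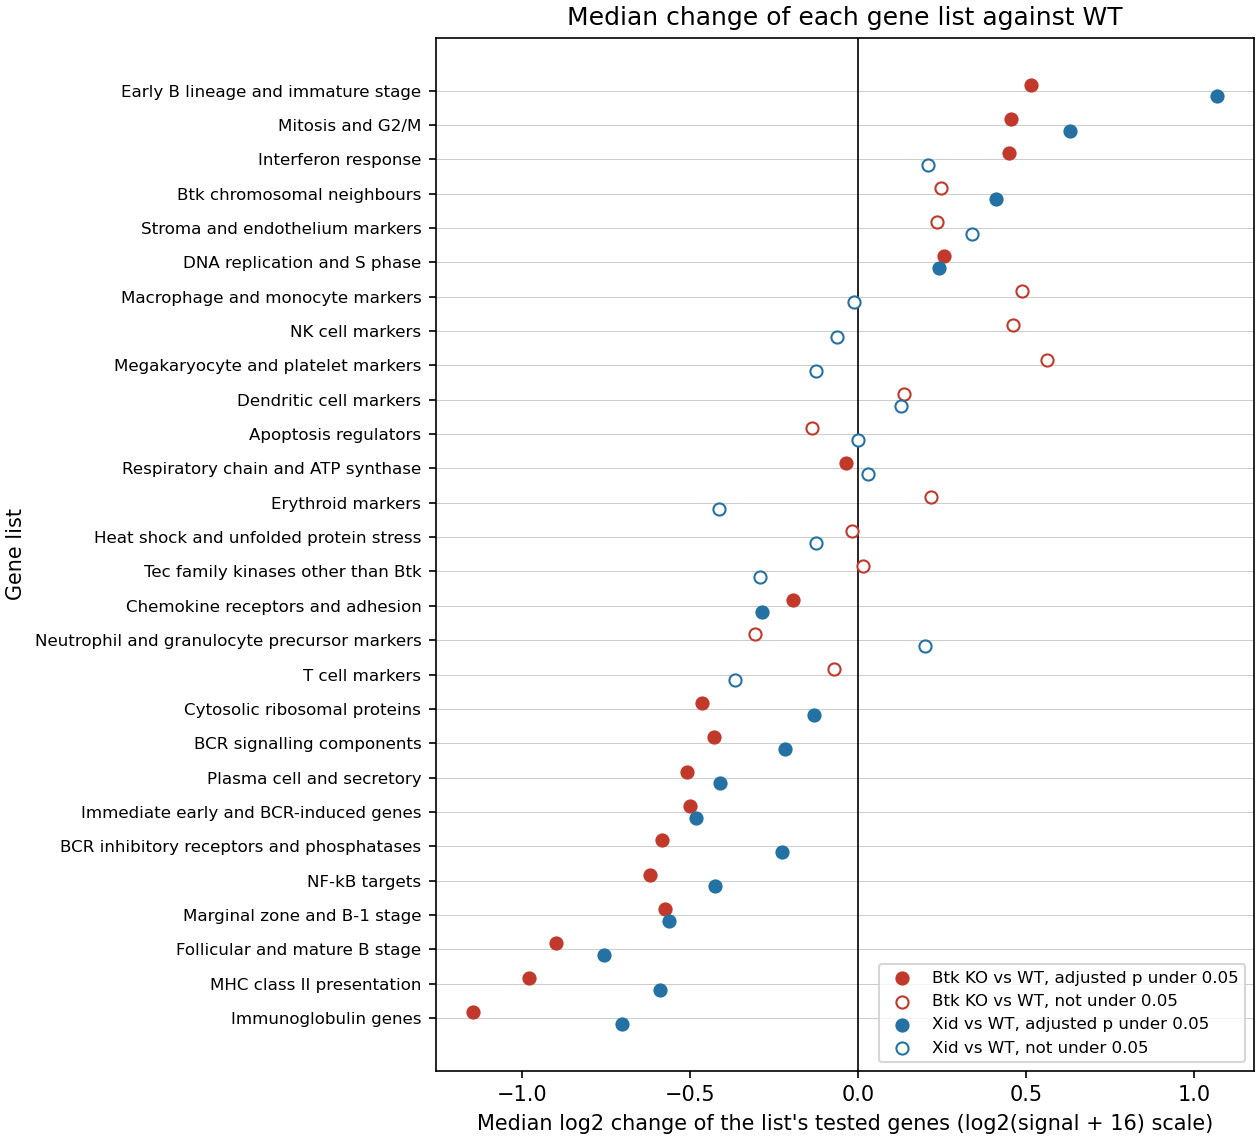
Median log2 change of each of the 28 gene lists in Btk KO vs WT (red) and Xid vs WT (blue); filled points had an adjusted p under 0.05 with a preset correlation. Follicular genes lay at -0.90 and -0.76 and early B lineage genes at 0.52 and 1.07; with an estimated correlation 0 lists passed.

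Xid vs WT asked what the mutant kinase changes where Btk RNA is kept. Xid cells had little Jchain RNA, as the knockout cells did, and a higher median of early B lineage genes, which was not called with an estimated correlation (adjusted p = 0.508). Jchain fell to a signal of 17.1 ± 1.98 (n = 2), a log2 change of -5.79 ± 0.203 (adjusted p = 0.000546). Dtx1 (-2.47 ± 0.275, adjusted p = 0.0347), Timd2 (-2.97 ± 0.291, 0.0225), the sialyltransferase gene St8sia6 (-2.48 ± 0.313, 0.0475), the extracellular matrix gene Reln (-2.40 ± 0.232, 0.0225) and Myo1e (-3.23 ± 0.318, 0.0225) fell as well, as did Ighg3 (-2.34 ± 0.294, 0.0475) of the immunoglobulin list. With a pseudocount of 1, 4 of the 24 named genes lost their call, Timd2 (adjusted p = 0.0792), St8sia6 (0.0623), Ighg3 (0.0598) and AF067061 (0.167), and the log2 change of Timd2 ran from -4.90 with 1 to -1.63 with 64. Erdr1 fell from 2127 ± 130 to 312 ± 40.5 (-2.71 ± 0.168, adjusted p = 0.00354). Mndal, a gene of the interferon-inducible p200 family, rose from 1.7 ± 1.98 to 1178 ± 299 (adjusted p = 0.000546). With its WT signal near 0, the log2 change is set by the pseudocount, at 8.97 with 1, 6.06 with 16 and 4.22 with 64. The peptide transporter Slc15a2 rose from a WT signal of 8.1 to 442, by 5.61, 4.25 and 2.81 with these pseudocounts. The carboxypeptidase inhibitor Lxn (3.30 ± 0.275), the glutamine transporter Slc1a5 (3.23 ± 0.197) and Rag2 of the early B lineage list (2.10 ± 0.228, adjusted p = 0.0321) rose too. All 24 named genes passed, with 12 higher by 2.10 to 6.06 and 12 lower by values from -5.79 to -2.34, but the other probe set of Lats1 (-0.45) and 1 of the 3 others of Lin7c (0.38) had the opposite sign. Limma called 58 of 22518 probe sets (30 higher, 28 lower; 43 genes), and 2128 had an unadjusted p under 0.05. This count was 743 without Btk KO replicate 1 and 714 without Btk KO replicate 2, each including the same 58, and 2 without either WT or either Xid array, namely Jchain and Mndal. At a log2 change of at least 1 without overlap, 529 probe sets differed, 263 higher and 266 lower. The 33.33% of unchanged probe sets that chance leaves without overlap holds for differences of any size, so it is not the chance rate for this count.

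The early B lineage list had its highest median in Xid, with 23 of 23 genes above 0 at 1.07 (adjusted p = 1.43e-14; adjusted p = 0.508 with an estimated correlation). Over the list alone 14 rose, among them Rag2, Erg (1.86 ± 0.239) and Enpep (2.73 ± 0.458). Over all genes Rag2 passed in the fit of 1 probe set per gene, and the same Erg probe set passed among all probe sets (adjusted p = 0.0482). Mitosis and G2/M genes were higher for 29 of 29 (median 0.63, adjusted p = 2.02e-16; adjusted p = 0.508 with an estimated correlation), and 16 rose over the list alone, such as Nek2 (0.89 ± 0.162), Top2a (0.86 ± 0.163) and Cdc20 (0.59 ± 0.115), but limma called 0 over all genes, with 18 at an unadjusted p under 0.05. DNA replication and S phase genes had a median of 0.24 (adjusted p = 4.95e-05; adjusted p = 0.727 with an estimated correlation), which was 0.14 without WT replicate 1, 0.08 without Xid replicate 1 and 0.38 without Xid replicate 2. The chromosomal neighbours of Btk had a median of 0.41 (adjusted p = 9.52e-05; adjusted p = 0.447 with an estimated correlation), with Tspan6 (1.64 ± 0.313), Bex1 and Sytl4 higher and Xkrx (-1.33 ± 0.249) lower over the list alone.

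Later stages and BCR-induced genes were lower in Xid. Follicular genes were below 0 for 19 of 19 (median -0.76, adjusted p = 2.18e-09; adjusted p = 0.508 with an estimated correlation), and 7 fell over the list alone, including Gpr183 (-1.72 ± 0.236), Ly86 (-1.46 ± 0.249) and Cr2 (-1.89 ± 0.499). The marginal zone and B-1 list had a median of -0.56 (adjusted p = 9.92e-07; adjusted p = 0.25 with an estimated correlation); 4 fell over the list alone, and 3 of these, Zbtb32, S1pr3 and Dtx1, over all genes. For Zbtb32 this holds at 1 probe set only, as in Btk-defective vs WT that probe set had -2.049 and its other probe set 0.521. Plasma cell and secretory genes had a median of -0.41 (adjusted p = 1.89e-08; adjusted p = 0.25 with an estimated correlation), with 5 lower over the list alone, including Ell2 (-0.85 ± 0.174) and Xbp1 (-0.47 ± 0.117), and Jchain over all genes. Medians were -0.59 for MHC class II genes (adjusted p = 1.47e-07), -0.70 for immunoglobulin genes (3.77e-07), -0.48 for immediate early genes (5.66e-08) and -0.23 for inhibitory receptors (0.0206), each with adjusted p = 0.508 with an estimated correlation. Of these, 2 class II genes, 2 immunoglobulin genes, 9 immediate early genes and 1 inhibitory gene fell over the list alone, and Nr4a1 (-1.88 ± 0.214) also over all genes. NF-kB targets had a median of -0.43 (adjusted p = 3.43e-05; adjusted p = 0.518 with an estimated correlation), with Ccnd2, Bcl3, Ebi3 and Icosl lower over the list alone. BCR components (-0.22, adjusted p = 0.0201; adjusted p = 0.745 with an estimated correlation), chemokine receptors (-0.29, adjusted p = 0.00781; adjusted p = 0.447 with an estimated correlation) and ribosomal genes (-0.13, adjusted p = 0.000193; adjusted p = 0.508 with an estimated correlation) had smaller medians. In the last, quantile normalization left -0.03 (not called), and the median was -0.07 without WT replicate 2 and -0.06 without Xid replicate 2. Without Xid replicate 1 the medians were -0.50 for follicular, -0.35 for marginal zone and -0.36 for class II genes, all called. Calls were lost for BCR components without WT replicate 1 (-0.17, adjusted p = 0.0663) or Xid replicate 1 (-0.14, 0.117), for inhibitory receptors without WT replicate 1 (-0.12, 0.172) or Xid replicate 1 (-0.11, 0.206; -0.37 without Xid replicate 2), and for chemokine receptors without WT replicate 2 (-0.22, 0.0589). Of the lists not called, the apoptosis regulators Bcl2 (-1.59 ± 0.235), Bid (-1.42 ± 0.261) and Bcl2l11 (-0.88 ± 0.147) fell over the list alone, and the markers of the 8 other cell types had medians from -0.42 (erythroid) to 0.34 (stroma).

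The change common to both Btk-defective genotypes was tested as their mean against WT. Jchain (-5.97 ± 0.176, adjusted p = 0.000168), LOC664787 (-2.99 ± 0.225), Timd2 (-3.06 ± 0.252), S1pr3 (-2.36) and Dtx1 (-2.52 ± 0.238) fell, and Igfbp4 (1.79 ± 0.155, adjusted p = 0.0224), Gfra2 (1.79 ± 0.182) and Adgrg1 (1.80 ± 0.206) rose. Among calls chosen after their values were seen, the lymphoid transcription factor gene Ikzf3 fell from 518 ± 10.8 in WT to 152 ± 28.5 in Btk KO and 154 ± 28.6 in Xid (-1.67 ± 0.180, adjusted p = 0.0386). The other probe set of Ikzf3 had -0.58, and the weakest of the 4 others of Gfra2 had 0.21. Early B lineage genes had a median of 0.79 (adjusted p = 2.18e-09; adjusted p = 0.508 with an estimated correlation), with 13 of 23 higher over the list alone, and follicular genes one of -0.71 (adjusted p = 1.06e-12; adjusted p = 0.508 with an estimated correlation), with 11 of 19 lower over the list alone. Limma called 0 of either over all genes, and 15 and 12 differed at an unadjusted p under 0.05. The follicular median was -1.20 without Btk KO replicate 2. Limma called 36 probe sets (16 higher, 20 lower; 30 genes), and a change in 1 genotype alone can pass this test, as for Mndal (2.97, adjusted p = 0.0164). The count was 739 without Btk KO replicate 1, 1590 without Btk KO replicate 2, and 1 without either WT or either Xid array.

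Changes in Btk KO and Xid were compared over all tested probe sets. The genotypes shared 3 calls, all lower, where independent calls would share 0.00497. Across probe sets, which are not independent replicates, the 2 sets of changes had r = 0.579 and a covariance of 0.092. Unchanged groups that share the same WT arrays gave a simulated mean r of 0.502 (range 0.481 to 0.522) and a covariance of 0.0354. The share of probe sets with the same sign in both, 67.1%, lay within the simulated range of 66 to 67.8%. The simulation gave each probe set the same spread in every genotype. The SD of the difference between replicates was 0.631 in Btk KO, 0.311 in WT and 0.310 in Xid. The simulated values are therefore not those of unchanged groups with these spreads, and they do not decide how much comes from shared controls. At 2-fold without overlap, 99 probe sets were higher and 149 lower in both, against 3.69 and 3.24 for independent sets (263 × 316 and 266 × 274 over 22518). The 2 WT arrays could not be divided between the comparisons, so part of the excess may come from the shared controls. The correlation was 0.415 without Btk KO replicate 2 and 0.484 without Xid replicate 1.

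**Figure D4:**
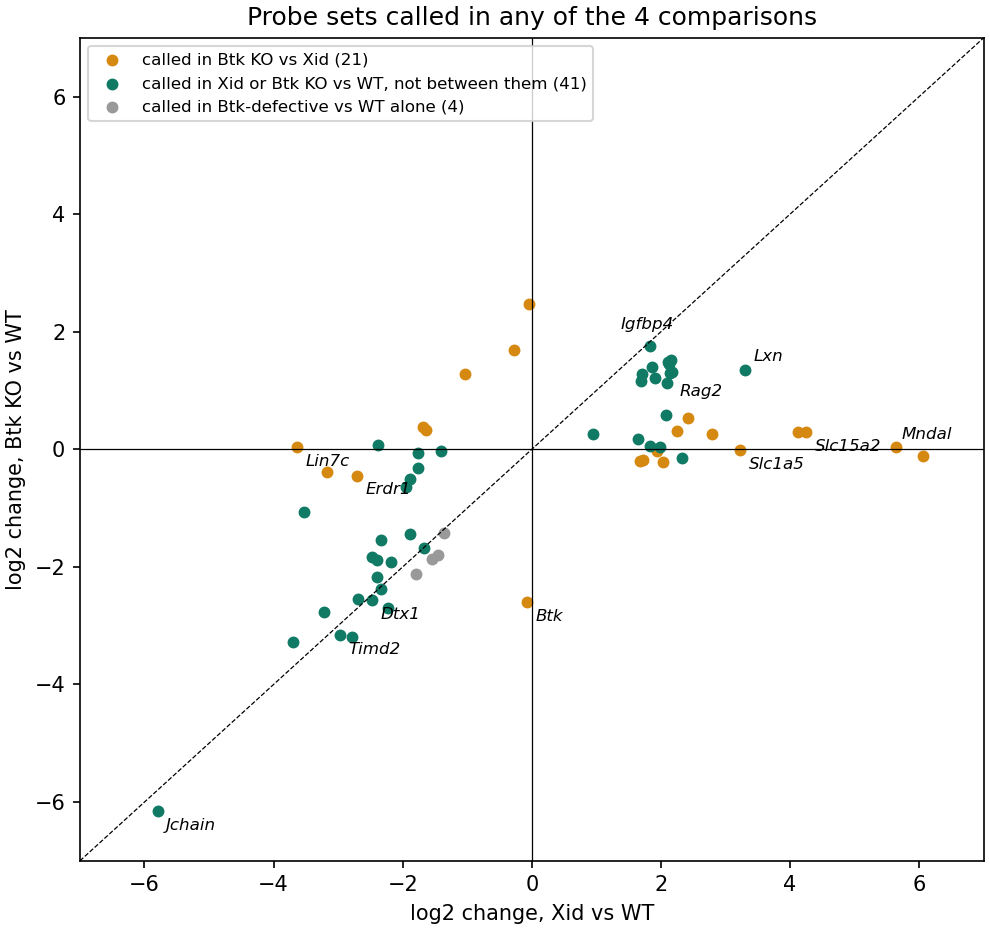
Log2 change in Xid vs WT (horizontal) and Btk KO vs WT (vertical) of every probe set called in any comparison, with the line of equal change dashed. Jchain, Timd2 and Dtx1 lay near that line; Mndal and Slc15a2 changed in Xid and Btk in Btk KO, among the 21 probe sets called between the 2 genotypes.

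Btk KO vs Xid asked whether absence of the kinase and its mutation act alike. Of the 58 probe sets called in Xid, 17 differed between the genotypes. Mndal (-6.17, adjusted p = 0.000962), Slc15a2 (-3.96, 0.0065), Slc1a5 (-3.24 ± 0.197, 0.0065) and Sertad4 (-2.52, 0.0146) were lower in Btk KO than in Xid, as was Btk (-2.52 ± 0.165, 0.0065). With mean Btk KO signals below 16, the sizes for Mndal (-9.81 to -4.25 with pseudocounts of 1 and 64), Slc15a2 (-5.01 to -2.70) and Sertad4 are set by the pseudocount. The cell polarity gene Lin7c (3.67 ± 0.258, adjusted p = 0.00824), Plppr1 (2.79 ± 0.306, 0.0496), Erdr1 (2.26 ± 0.168, 0.0103), the adhesion receptor gene Adgrg3 (2.33 ± 0.211, 0.0311) and Tox2 (1.97 ± 0.207, 0.0414) were higher. With a pseudocount of 1, Ppcdc fell below the filter on low values and 5 of the other genes that passed lost their call, among them Tox2 (adjusted p = 0.0667). Plppr1, with a mean Xid signal of 5.9, had 4.29 with a pseudocount of 1 and 1.52 with 64, where it lost its call (adjusted p = 0.105). Among the genes that passed, the other probe set of Lats1 (0.13) and of Snrnp200 (0.01), 1 of the 3 others of Lin7c (-0.76) and 1 of the 2 others of Pisd-ps3 (0.47) had the opposite sign. Jchain (-0.36 ± 0.203, adjusted p = 0.597), Dtx1 (-0.09, 0.928) and Igfbp4 (-0.07, 0.912) did not pass, which does not show that they were equal. Of the 24 named genes, 6 passed as higher and 10 as lower. The other 8 did not pass, among them Tnfrsf14 (3.12, adjusted p = 0.0597) and Stk4 (-1.42, 0.0541, with 0.16 at 1 of its 2 other probe sets). The size for Tnfrsf14 also depends on the pseudocount, at 5.54 with 1 (adjusted p = 0.0218) and 1.65 with 64 (0.136). Limma called 21 probe sets, 8 higher and 13 lower (3 and 13 after quantile normalization, 3 and 16 after median centring), and 2384 had an unadjusted p under 0.05. The count was 112 without Btk KO replicate 1, 1872 without Btk KO replicate 2, 2 without either WT array and 1 without either Xid array. At a log2 change of at least 1 without overlap, 262 were higher and 82 lower (154 and 115 after quantile normalization, 131 and 165 after median centring). The 33.33% that chance leaves without overlap again holds for differences of any size and is not the chance rate for these counts.

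Between the genotypes, early B lineage genes had a lower median in Btk KO, with 19 of 23 below 0 (-0.48, camera adjusted p = 3.91e-07, or 0.508 with an estimated correlation). Mitosis genes also had a lower median (-0.18, adjusted p = 0.000214, or 0.727 with an estimated correlation), which was -0.08 after quantile normalization and -0.36 after median centring. Limma called 0 members of these lists over the list alone or over all genes, and 5 early and 5 mitosis genes were lower at an unadjusted p under 0.05. Without Btk KO replicate 1 the early median was -0.09 and not called (adjusted p = 0.116), and without Btk KO replicate 2 it was -0.93. The mitosis call was lost without Btk KO replicate 2 (-0.07, adjusted p = 0.339) or Xid replicate 1 (-0.07, 0.48), and the median was -0.28 without Btk KO replicate 1 and -0.37 without Xid replicate 2. Ribosomal genes had a median of -0.32 (adjusted p = 2.53e-19; adjusted p = 0.301 with an estimated correlation), and of -0.04, not called (0.13), after quantile normalization. Respiratory chain genes had one of -0.12 (adjusted p = 0.000843; adjusted p = 0.563 with an estimated correlation), which quantile normalization turned to 0.04, not called (0.0742). The latter was -0.19 without Btk KO replicate 1 and -0.05 without Btk KO replicate 2 (adjusted p = 0.522). In the heat shock list, which did not pass (adjusted p = 0.646), Hspb1 (1.04 ± 0.251) rose and Hspa8 (-0.54 ± 0.110) fell over the list alone.

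The other lists called between the genotypes moved with Btk KO replicate 1, the array with higher markers of other cell types than replicate 2. BCR components had a median of -0.25 (adjusted p = 0.00432; adjusted p = 0.727 with an estimated correlation), which was 0.11 without that array, -0.62 without Btk KO replicate 2 and not called without Xid replicate 2 (-0.26, adjusted p = 0.0696). MHC class II genes had a median of -0.22 (adjusted p = 0.00492; adjusted p = 0.727 with an estimated correlation), against 0.04 without Btk KO replicate 1, -0.54 without Btk KO replicate 2, -0.49 without Xid replicate 1 and -0.01 without Xid replicate 2 (adjusted p = 0.782). Inhibitory receptors (-0.32, camera adjusted p = 0.0404, or 0.53 with an estimated correlation) were not called without Btk KO replicate 1 (-0.09), Btk KO replicate 2 (-0.43) or Xid replicate 2 (-0.14). Their median was -0.16 after quantile normalization, and 0.009 with all probe sets of the list, not called (adjusted p = 0.089). Megakaryocyte markers (0.56, adjusted p = 0.0395; adjusted p = 0.694 with an estimated correlation) were not called without Btk KO replicate 1 (0.05) or Xid replicate 2 (0.49, adjusted p = 0.119), and had 1.06 without Btk KO replicate 2. The chromosomal neighbours (-0.19, adjusted p = 0.0329; adjusted p = 0.508 with an estimated correlation) were not called without Btk KO replicate 1 (-0.09) or Xid replicate 1 (-0.14, adjusted p = 0.0882).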

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

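The 9 tests of explanations in this part were chosen after the results were seen, whereas the tests of Btk KO vs Xid were planned.

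The effects of Btk KO and Xid differed in a direct test at 16 genes with 1 symbol. Log2 differences were 3.67 for Lin7c, 2.79 for Plppr1, 2.33 for Adgrg3, 2.26 for Erdr1, 2.07 for Ppfia4 and 1.97 for Tox2. They were -6.17 for Mndal, -3.96 for Slc15a2, -3.24 for Slc1a5, -2.52 for Btk, -2.52 for Sertad4, -1.97 for Pisd-ps3, -1.94 for Snrnp200, -1.91 for Ppp5c, -1.88 for Lats1 and -1.88 for Ppcdc. Sizes for genes with a signal below 16 in a group, such as Mndal, depend on the pseudocount. Outside the tested probe sets, the 3' control probe set of the transferrin receptor had a signal of 113.5 and 62.2 on the Btk KO arrays against 38.6 and 34.4 in WT, a ratio of 2.41.

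Some changes in Xid were not shared by Btk KO. For Mndal, an interferon response across the tested interferon list in the Xid cells is argued against by a median of 0.206 (SD of its members 0.370). The change in Mndal was at least 4.22 over pseudocounts of 1, 16 and 64. A probe set with several symbols, Ifi203 among them, was left out of that list. Chosen after its values were seen, it rose from 11.6 in WT to 464 in Xid (log2 change 4.13, limma adjusted p = 0.00354). Its mean in Btk KO was 18.35. A response limited to Mndal and such genes was not tested. Strain variants under single probe sets cannot be told apart from changes in expression: another probe set moved less than 50% as far for 7 of 9 genes against 5 of 11 for shared changes (Fisher exact p = 0.197), and the genotypes also differ in strain history, while the Xid allele itself stays open, untested. The RNA of other cells in Btk KO replicate 1 is argued against as the whole cause at the 17 probe sets called both in Xid vs WT and between the genotypes, because without that array each kept at least 90.7% of its Btk KO vs Xid difference while the neutrophil median in Btk KO vs WT went from -0.31 to -1.84, although such calls favour probe sets at which the 2 Btk KO arrays are alike. For the other changes in Xid the RNA of other cells cannot be told apart. A fit of WT and Xid alone called 738 probe sets, of which 334 moved less than 50% as far in Btk KO replicate 1. Of these 334, 38.9% did so in replicate 2 too, between the bounds of 20 and 80% set for this test. Of all 738, 229 did so in replicate 2. A count of probe sets called without Btk KO replicate 1 was tried too and set aside, because a smaller spread alone raises it.

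Btk KO replicate 1 differed from Btk KO replicate 2. A mislabelled genotype is argued against by its Btk signal of 158.8, where the lowest WT or Xid array had 1041.3. This signal does not test whether another cell fraction of Btk KO mice was labelled as T1 cells. Degraded RNA in Btk KO replicate 1 is argued against by its Gapdh 3' to 5' ratio of 1.705, below the 1.783 to 2.339 of the other arrays. A candidate explanation is more RNA of cells other than B cells in Btk KO replicate 1, less of it in replicate 2, or both. A sort with purity above 92% leaves room for such cells on any array. The 8 lists of other cell types, fixed before the values were seen, had higher medians in replicate 1. Of their genes, 2 T cell, 1 neutrophil, 2 dendritic cell and 1 stroma gene are in another list too. Replicate 1 lay above the mean of WT and Xid in 8 of 8 lists, while replicate 2 lay below it in 7. Signals in replicates 1 and 2 were 714 and 34.4 for Gzma (at most 317 in WT and Xid) and 152 and 6.8 for Cd3g (at most 86.8), but 4296 and 1135 for S100a8 (3540 to 5137), 4460 and 1307 for Ngp (3592 to 4817) and 3556 and 694 for Camp (2394 to 3773), where replicate 2 was the one apart.

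Genes of late stages were lower and genes of early stages higher in both genotypes as lists with a preset correlation, and 0 of these lists were called with an estimated correlation (adjusted p from 0.25 to 0.674), so the shift itself is uncertain. Less B cell RNA in the Btk-defective samples would by itself lower early genes as well, whereas their median was 0.791. The SE of the mean (0.132) is taken over genes of the same arrays, not over samples. With an estimated correlation camera did not call the early list (adjusted p = 0.508), so these values do not decide against less B cell RNA. Without Btk KO replicate 1, the array with higher markers of other cell types, the Btk KO vs WT medians were -0.559 for follicular and 0.885 for early genes. These rest on 1 Btk KO array and were not tested with an estimated correlation. They therefore do not decide against the RNA of other cells in that array as the whole cause in Btk KO. That array takes no part in the Xid vs WT medians, -0.757 for follicular and 1.066 for early genes. A different mix of stages within the sorted T1 cells and a change of expression in the same cells may each give this pattern, and neither was tested.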

How the results depend on the processing

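The crossed replicate block was chosen after the results were seen, and the other alternatives were planned. Where no cause is given, the cause was not tested.

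Counts moved with the fit. For Btk KO vs WT, 4 calls became 2 (pseudocount 1), 7 (pseudocount 64), 9 (median centring), 2 (no filter on low values), 2 (one probe set per gene, fewer tested) and 1 (fit on the 2 groups compared). For Xid vs WT, 58 became 11 (no filter), 19 (stricter filter by mean), 646 (array weights), 24 (one probe set per gene) and 738 (fit on the 2 groups compared). For Btk KO vs Xid, 21 became 8 (no filter), 6 (stricter filter), 7 (one probe set per gene) and 2 (fit on the 2 groups compared). For Btk-defective vs WT, 36 became 1 (pseudocount 1), 1 (no filter), 7 (stricter filter) and 249 (array weights). At 2-fold without overlap, pseudocount 1, pseudocount 64, the stricter filter and one probe set per gene gave 1742, 171, 281 and 339 for Btk KO vs WT, 1164, 222, 290 and 316 for Xid vs WT, and 1239, 77, 91 and 168 for Btk KO vs Xid. A small pseudocount lets low signals differ by 2-fold, and without detection calls signal over background limits what these say.

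The replicate numbers do not pair the arrays, with correlations of deviations of -0.251, -0.344 and 0.166. With a replicate block the counts were 1, 22, 8 and 10 in the order above, and Btk was -2.60 (adjusted p = 0.061). The crossed replicate block gave 20, 88, 13 and 84.

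Leaving out 1 array leaves a lone sample that is assumed to vary like the other groups. Counts ran from 1 to 2685 (Btk KO vs WT), 2 to 743 (Xid vs WT), 1 to 1872 (Btk KO vs Xid) and 1 to 1590 (Btk-defective vs WT). Btk ran from -2.719 to -2.482 and the correlation of the Btk KO and Xid changes from 0.415 to 0.657.

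Of 112 list tests, 56 were called, against 0 with an estimated correlation, 7 with fry and 49 to 69 otherwise. Medians of called lists changed sign in 7 cases, in 5 of them with the direction of the test. The other 2 were respiratory chain genes in Btk KO vs WT without Btk KO replicate 2 (0.0256) and inhibitory receptors in Btk KO vs Xid with all probe sets of the list (0.00894). Respiratory chain genes had 0.111 (Btk KO vs WT) and 0.0395 (Btk KO vs Xid) after quantile normalization. Leaving out single arrays gave S phase genes medians from -0.0369 to 0.499 (Btk KO vs WT), BCR components -0.622 to 0.108 and MHC class II genes -0.544 to 0.0362 (Btk KO vs Xid), with the reversed sign in each without Btk KO replicate 1. Called lists kept direction and call in 630 comparisons with an alternative and lost the call in 149. Named genes, called or not, kept their direction and side of the threshold in 592, gained a call in 69, lost it in 200 and reversed in 0; a named gene below the filter on low values under an alternative, as Ppcdc with pseudocount 1, has no value there.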

Other observations

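No test was run for this part, which gives values alone. Signals of different probe sets are not comparable as amounts of RNA.

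Transcripts of granulocyte precursors differed between arrays. S100a8 had a signal of 3540 and 4651 on the WT arrays, 5137 and 4366 on the Xid arrays, and 4296 and 1135 on the Btk KO arrays. For Camp these were 2394 and 3773, 3491 and 2907, and 3556 and 694.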
